A study of Mus musculus with 10 samples.

How the data were processed

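CNS-associated macrophages, the macrophages that live at the borders of the brain such as the meninges and the perivascular spaces, were isolated by fluorescence-activated cell sorting from the brains of C57BL/6N mice aged 6 to 8 weeks, per the labels. The sort gate is not given in the sources used here. The mice carried the Mrc1-CreERT2 allele on both chromosomes (4 mice), on a single chromosome (3 mice) or on neither (3 mice), and each library came from an individual mouse. Per the labels' protocols, libraries were made from 500 pg of total RNA with the SMARTer Ultra Low Input kit, which does not mark the strand, followed by Nextera XT, in 1 batch.

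The authors deposited a single table of whole-number read counts per gene symbol, with a column for each of the 10 libraries. Reads were processed with bcl2fastq 2.20, STAR 2.7.8a and featureCounts 2.0.2, per the submitters' processing notes. The genome build, the gene annotation and the strand setting are not given in the sources used here, so no coordinates are reported, and the reads of overlapping or antisense genes and of near-identical gene copies such as the haemoglobin genes cannot be told apart. Of the symbols in the table, 93.5% matched a name in GENCODE vM21, which was used for names only. The order of genes next to Mrc1 was taken from RefSeq on GRCm38.p6.

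The table holds 53546 genes, of which 22778 had a count in any library. Library totals ran from 22986972 to 36575446 counts. Genes with too few counts were removed with filterByExpr by genotype (minimum count 10, minimum total 15), which left 14023 genes holding 99.9% of all counts. Trimmed-mean-of-M-values factors scaled the libraries, and counts per 1000000 counts of a library (CPM) use them. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with robust dispersion estimates, all 10 libraries in the fit and genotype as the only term. P-values were adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the test's F value. A fold against a genotype with 0 counts in all of its libraries is given as a bound against 3 counts over the group. PCR reads without molecular identifiers are not independent molecules, so such bounds cover counting error only.

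Of 34 gene lists covering cell types, macrophage functions and technical states, 30 had at least 3 tested genes and were tested with camera in limma 3.58.1, with a preset correlation of 0.01, on voom log2 values computed from the deposited counts. List p-values were adjusted over the 30 lists. The list tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, in a single direction. The separation of the 3 genotypes was measured with a pseudo-F statistic on log2 CPM with a prior count of 2 over the 500 most variable genes, with an exact permutation test over all 4200 assignments of the libraries.

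The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Mrc1 and Esr1, up to 10 called genes with the smallest p in each direction (filled to 5 with uncalled genes where fewer passed), and the 4 most abundant members of each list described. Any other gene named was chosen after its values were seen. The values of some genes that the rule or the lists include are not reported here. The alternatives were DESeq2's size factors in edgeR, no count filter, a stricter filter (at least 1 CPM in 3 libraries and a mean count of 10), DESeq2 1.42.0, limma-voom, a fit without robust estimation, the title letter as a covariate, the replicate number as a block, a fit on only the 2 genotypes compared, and each library left out in turn. A title letter by genotype interaction, the DESeq2 counts over other splits of the libraries and a fit without Mrc1, also over the splits, were added after the data had been seen.

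The tests were tried on counts simulated from the real libraries, with 200 genes changed. For homozygous against wild type, edgeR called 28% of the genes changed 4-fold and 2% of those changed 2-fold among 13130 genes, with 2 false calls. Among genes over 20 CPM it called 66.7% of those changed 4-fold. DESeq2 made 120 calls on the same counts, of which 50.8% were false. The counts were drawn once per comparison with edgeR's own dispersion estimates, so the trial may favour edgeR over DESeq2. Figures were drawn with matplotlib.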

Results

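Bulk RNA sequencing profiled CNS-associated macrophages sorted from the brains of individual untreated mice of 3 genotypes. The Mrc1-CreERT2 allele carries CreERT2, a Cre recombinase fused to the ligand-binding part of the oestrogen receptor, and by its name sits at Mrc1, the gene of the mannose receptor CD206. There were 4 homozygous mice, 3 heterozygous mice and 3 wild-type mice. The heterozygous replicates are numbered 1, 2 and 4, and the deposited counts hold none with the number 3. The comparisons ask how carrying a single copy or a pair of copies of the allele affects the transcripts of these macrophages without any induction of Cre. Libraries held 27358042 to 36575446 counts in homozygous, 22986972 to 32326603 in heterozygous and 28668839 to 32931690 in wild-type mice. No pair of libraries of a genotype agreed within counting noise, with a chi-square per gene of at least 87.1. It was 87.1 to 123 in homozygous, 110 to 137 in heterozygous and 181 to 204 in wild-type pairs. Wild-type replicates therefore agreed least with each other, and how far this affects the comparisons was not tested. The letter m or f in the sample titles matched the counts of Xist or of the Y-linked genes in 10 of 10 libraries, and each genotype held both letters. The titles also carry a number the labels do not explain, which was higher in 3 of the 4 homozygous mice than in any mouse of the other genotypes.

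Mrc1 counts followed the number of unmodified alleles. Mrc1 was at 3481 ± 365 CPM (SD, n = 3) in wild-type, 2153 ± 153 CPM (SD, n = 3) in heterozygous and 489 ± 48.6 CPM (SD, n = 4) in homozygous libraries, and the 3 genotypes did not overlap. Heterozygous libraries therefore held 61.8% and homozygous libraries 14.1% of the wild-type level. The residual counts in homozygous libraries were far above the detection limit, with 12153 to 18496 counts per library. A gene-level table does not show which part of Mrc1 they cover. Esr1, the mouse gene of the oestrogen receptor whose ligand-binding part resembles that in CreERT2, was at 44.2 ± 6.17 CPM (SD, n = 4) in homozygous, 32.8 ± 11.7 CPM (SD, n = 3) in heterozygous and 25.7 ± 4.04 CPM (SD, n = 3) in wild-type libraries. Its log2 fold change of 0.78 (SE 0.28) between homozygous and wild-type libraries did not pass edgeR's test over all genes (adjusted p = 0.606).

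**Figure D1:**
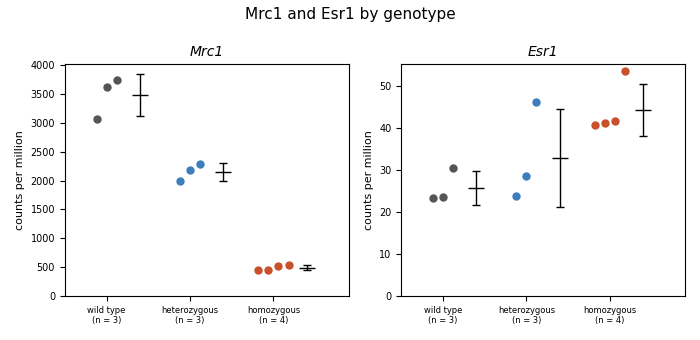
CPM of Mrc1 and Esr1 (y axis, from 0) by genotype, with a point for each library and the mean ± SD beside it. Mrc1 lies at 441 to 542 CPM in the 4 homozygous, 1985 to 2286 CPM in the 3 heterozygous and 3065 to 3748 CPM in the 3 wild-type libraries.

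Between homozygous and wild-type macrophages, Mrc1 fell by 2.83 on the log2 scale (SE 0.11), and few other genes passed the test. Ccr2, a chemokine receptor of monocytes and of cells derived from them, fell from 129 ± 53.2 CPM (SD, n = 3) to 7.12 ± 1.60 CPM (SD, n = 4), a log2 change of -4.18 (SE 0.36). Cd52, a small surface glycoprotein of leukocytes, Slamf9, a receptor of the SLAM family, Coro1a, an actin-binding protein of leukocytes, and Clec12a, an inhibitory C-type lectin of myeloid cells, fell by 1.39, 2.29, 1.52 and 1.22. Lyve1, a hyaluronan receptor that marks a subset of these border macrophages, rose from 631 ± 5.62 CPM (SD, n = 3) to 1141 ± 90.0 CPM (SD, n = 4), a log2 change of 0.85 (SE 0.10). Hgsnat, a lysosomal acetyltransferase of heparan sulfate breakdown, rose by 0.87 (SE 0.11).

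These were 9 genes called of 14023 tested, 3 higher and 6 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The adjusted p was 1.28e-06 for Mrc1, 0.00216 for Ccr2, 0.0215 for Lyve1, 0.0315 for Hgsnat, Cd52, Slamf9 and Coro1a, and 0.0490 for Clec12a. The third higher gene was Gja1, which encodes the gap junction protein connexin 43 of astrocytes. It had 0 counts in all 3 wild-type libraries and 10.5 ± 4.51 CPM (SD, n = 4) in homozygous ones, at least 325-fold higher against 3 counts over the group (adjusted p = 0.0315). Heterozygous libraries held 8.89 to 13.5 CPM of Gja1, which overlapped the homozygous values. Stab1, a scavenger receptor (log2 fold change 0.54, adjusted p = 0.0567), and Npl, an enzyme of sialic acid breakdown (0.78, adjusted p = 0.0642), came next among the higher genes and did not pass. At an unadjusted p under 0.05 there were 1054 genes, 639 higher and 415 lower, where chance alone gives 701. The median SE of a log2 fold change was 0.61 over all genes and 0.18 over the 1797 genes above 100 CPM.

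Only Mrc1 and Ccr2 were called with each of the 10 libraries left out in turn. The count fell to 2 without homozygous replicate 1, 2 or 4 or wild-type replicate 1, to 3 without homozygous replicate 3 or heterozygous replicate 2, to 4 without heterozygous replicate 1 or wild-type replicate 2 and to 5 without heterozygous replicate 4, and was 12 without wild-type replicate 3, of which 8 were higher and 4 lower and 4 were shared with the 9. The count was 2, both lower, with only these genotypes in the fit, 17 with the title letter in the fit (3 higher and 14 lower), and 283 with DESeq2 (182 higher and the rest lower), whose calls on simulated counts for this comparison were false in 50.8% of cases. Limma-voom called 9 genes (4 higher and 5 lower), 6 of them shared with edgeR, and did not call Ccr2 (adjusted p = 0.0806, and up to 0.141 over the alternatives), Gja1 or Clec12a.

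**Figure D2:**
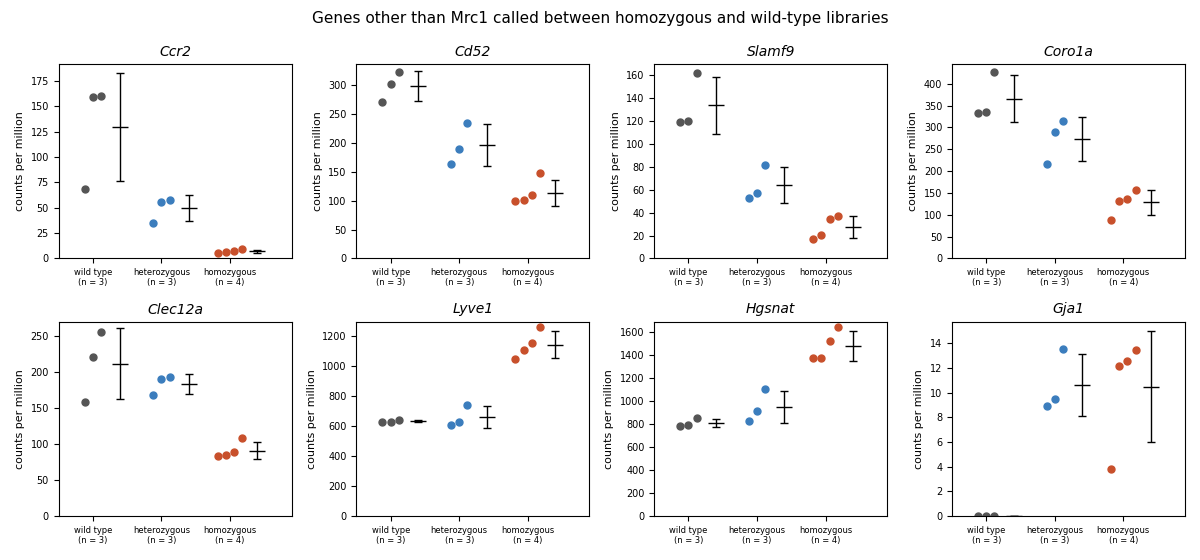
CPM (y axis, from 0) of the 8 genes other than Mrc1 called between homozygous and wild-type libraries, with a point for each library and the mean ± SD beside it, in all 3 genotypes. Ccr2 lies at 5.72 to 9.29 CPM in the 4 homozygous libraries and at 68.0 to 161 CPM in the 3 wild-type libraries.

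Genes of MHC class II antigen presentation were lower as a group in homozygous macrophages. Of the 14 tested members none passed over all genes, all 14 had a fitted value below 0 and 6 were lower when adjusted over the list alone (Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and H2-DMb1). H2-Aa was at 1171 ± 564 CPM (SD, n = 4) in homozygous and 4815 ± 1781 CPM (SD, n = 3) in wild-type libraries, a log2 fold change of -2.04 (SE 0.45). H2-Ab1 (-1.99, SE 0.47) and Cd74, the invariant chain (-1.58, SE 0.42), had similar values, and Ctss, a protease of the same pathway, had -0.24 (SE 0.12). The list median was -1.35, and camera called the list (adjusted p = 9.22e-12), also with an estimated correlation (adjusted p = 0.0261). Among B cells, which also bear MHC class II, 8 of 12 tested markers were fitted below 0, and Ighm (-0.93, SE 0.20) and Cd22 (-1.35, SE 0.30) were lower adjusted over the list alone, with none passing over all genes. Ighm was at 258 ± 58.1 CPM (SD, n = 4) in homozygous and 493 ± 112 CPM (SD, n = 3) in wild-type libraries, and Cd79b, the most abundant other member, had -0.26 (SE 0.27). The B cell list had a median of -0.83, a mean of 1.08 (3 members had 0 counts in wild type) and camera direction down, and was not called (adjusted p = 0.0542, and adjusted p = 0.485 with an estimated correlation), but was called lower with the stricter count filter, with the title letter in the fit, and without homozygous replicate 3 (adjusted p = 0.00918), homozygous replicate 4 (adjusted p = 0.00447) or wild-type replicate 1 (adjusted p = 0.000668). The 18 genes of MHC class I had a median of -0.03, a mean of 0.01 and camera direction down, and were not called (adjusted p = 0.376).

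Markers of CNS-associated macrophages other than Mrc1 were higher as a group. Of the 33 members, Lyve1 rose and Mrc1 fell over all genes, and adjusted over the list alone 11 were higher (among them Stab1, Dab2, Pf4 and Cd163) and 2 lower (Mrc1 among them). The list median was 0.22, and camera called the list higher (adjusted p = 1.91e-06), also with an estimated correlation (adjusted p = 0.0261). The most abundant members, Apoe, Lyz2, Dab2 and F13a1, had log2 fold changes of 0.20, -0.16, 0.44 and 0.39, and none passed over all genes. Both of these lists were called with each library left out.

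The microglia list had a median of -1.02 over 20 genes and was called lower by camera (adjusted p = 9.72e-07), but not with an estimated correlation (adjusted p = 0.39). Among its abundant members, Fcrls had a log2 fold change of 0.19, Cx3cr1 of -0.17 and P2ry13 of 0.17, and none of these passed. Adjusted over the list alone, 8 members were lower and 1 higher. Tmem119, a microglial surface protein chosen after its values were seen, was at 111 ± 21.2 CPM (SD, n = 4) in homozygous libraries, and at 258, 347 and 824 CPM in the 3 wild-type libraries.

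Interferon-response genes had a median of -0.42, with 29 of 30 fitted below 0 and 0 passing over all genes or over the list alone (camera adjusted p = 1.27e-05, and adjusted p = 0.43 with an estimated correlation). Ifi27l2a (-0.81) and Oasl2 (-0.72) were among the most abundant members. The monocyte list (median -1.40 over 10 genes, of which Ccr2 fell) and the inflammatory cytokine list (median -0.32 over 23 genes) each had an adjusted p of 0.0263 by camera. With an estimated correlation these became adjusted p = 0.264 and adjusted p = 0.19. The iron and haem list was called higher (median 0.18 over 16 genes, adjusted p = 0.0245, and adjusted p = 0.39 with an estimated correlation), with Cd163 at 0.49 and Trf at 0.26. Without homozygous replicate 2 only 4 lists were called, because the monocyte, inflammatory cytokine and iron lists no longer passed. The monocyte list was also lost without wild-type replicate 3, the interferon and iron lists without wild-type replicate 1, and the inflammatory cytokine list without homozygous replicate 3 or wild-type replicate 2.

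The other 23 lists tested were not called, with camera adjusted p from 0.0542, for the B cell and cell cycle lists, to 0.989. They included endothelial, meningeal fibroblast, astrocyte, oligodendrocyte, neuron, choroid plexus, erythroid, T and NK cell, B cell and dendritic cell markers. Some gained a camera call in alternatives. The cell cycle list (median -0.96, 28 of 32 fitted below 0) was called lower with the title letter (adjusted p = 0.0041), the replicate block (0.0035) and without wild-type replicate 1 (0.000698), among others. The T and NK cell list was called lower without wild-type replicate 2 (0.000171), dissociation stress lower without wild-type replicate 3 (9.8e-05) and erythroid higher with the replicate block (4.7e-05). Markers of lysosome and phagocytosis (median 0.08 and mean -0.07 over 40 genes, camera direction up, adjusted p = 0.433) and of oxidative phosphorylation (0.08 over 44 genes, adjusted p = 0.544) were also not called. Among the neutrophil list, with too few tested genes for camera, Mmp9, a secreted protease, had a log2 fold change of 1.41 (SE 0.30) that did not pass over all genes (adjusted p = 0.262). Wild-type libraries correlated less with the other libraries (mean r 0.808 ± 0.0090, SD, n = 3) than homozygous ones did (0.834 ± 0.0057, SD, n = 4). The two-sided exact permutation p was 0.0286, the smallest that 35 splits allow. Each mean r also covers libraries of the same genotype, of which a homozygous library has more, so group size may add to the gap.

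**Figure D3:**
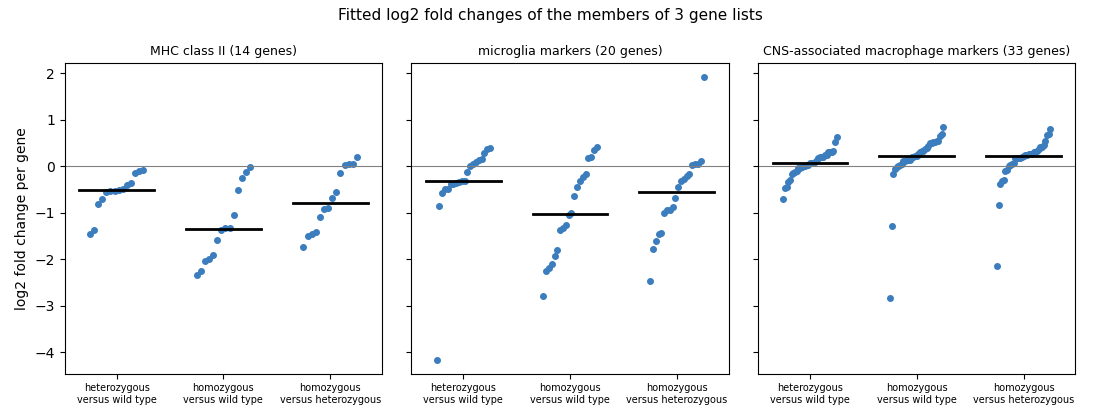
Fitted log2 fold change of each tested gene (y axis, a point per gene, ordered by value) in the MHC class II, microglia and CNS-associated macrophage lists for the 3 comparisons, with the list median as a bar. Between homozygous and wild-type libraries the medians are -1.35, -1.02 and 0.22, and the lowest point among the macrophage markers is Mrc1 at -2.83.

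In heterozygous macrophages no gene passed the test against wild type, Mrc1 included. Mrc1 had a log2 fold change of -0.69 (SE 0.11, n = 3 against 3), lower in 3 of 3 heterozygous libraries than in any wild-type library, with an unadjusted p of 8.54e-05 and an adjusted p of 0.30 by edgeR's quasi-likelihood test over 14023 genes. Ccr2 was at 49.7 ± 12.6 CPM (SD, n = 3), below the 68.0 CPM of the lowest wild-type library, and Lyve1 at 659 ± 72.8 CPM (SD, n = 3) overlapped the wild-type values. The genes with the smallest p after Gja1 were Zfp420, Scrn2, Ubr2 and Ap5b1 among the higher and Kptn, Frmd6, Armc9 and Unc45a, besides Mrc1, among the lower, and none passed. Ubr2, a ubiquitin ligase, had a log2 fold change of 1.10 (SE 0.22), and Frmd6 had -1.91 (SE 0.30).

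The count of 0 called genes by edgeR stood beside 816 genes at an unadjusted p under 0.05, where chance gives 701. It was also 0 with limma-voom and 233 with DESeq2, which on simulated counts for this comparison made 57.8% false calls. Adjusted over the list alone, Mrc1 passed in the CNS-macrophage list, Ccr2 in the monocyte list and Gja1 in the astrocyte list. The MHC class II list was called lower by camera (median -0.51, 14 of 14 fitted below 0, adjusted p = 6.91e-05), and so was the interferon list (median -0.37, 22 of 30 fitted below 0, adjusted p = 0.000963). With an estimated correlation they became adjusted p = 0.468 and adjusted p = 0.867. H2-Aa had a log2 fold change of -0.55 (SE 0.48) and Cd74 of -0.50 (SE 0.45). Neither list was called without heterozygous replicate 2, and the interferon list was lost without wild-type replicate 1. The number of called lists was 6 without wild-type replicate 1, 4 without wild-type replicate 2 and 5 without heterozygous replicate 4. The CNS-macrophage list had a median of 0.06 and was not called (adjusted p = 0.619).

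Against heterozygous macrophages, homozygous ones differed in 3 called genes. Mrc1 fell by 2.14 (SE 0.10, adjusted p = 1.76e-05), Ccr2 fell by 2.80 (SE 0.34, adjusted p = 0.0421) and Lyve1 rose by 0.79 (SE 0.10, adjusted p = 0.0421), with n = 4 against 3 and edgeR's quasi-likelihood test. Kptn, which had 0 counts in all 3 heterozygous libraries, Frmd6 (1.70), Cd38 (0.55) and Hgsnat (0.64) came next among the higher genes, and Clec12a (-1.02), Cd9 (-1.95) and Tgfbr1 (-0.72) among the lower. None of these passed. There were 681 genes at an unadjusted p under 0.05, against 701 by chance. Only Mrc1 was called when any of 9 libraries was left out, and Mrc1 and Ccr2 without wild-type replicate 1. Only Mrc1 was also called without robust estimation, with the title letter in the fit, or with only these genotypes in the fit. DESeq2 called 129. Limma-voom called Mrc1 and Lyve1 but not Ccr2 (adjusted p = 0.569, the highest over the alternatives). With Mrc1 left out before the fit edgeR called 0 genes, since Ccr2 and Lyve1, with log2 fold changes of -2.80 and 0.79, both had an adjusted p of 0.0634.

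Of the 30 lists, camera called 3 higher and 8 lower between homozygous and heterozygous libraries, and none held with an estimated correlation. The CNS-macrophage list (median 0.21, adjusted p = 5.91e-05) came closest, with an adjusted p of 0.0521 with an estimated correlation, and the inflammatory cytokine list (median -0.76, 20 of 23 fitted below 0, adjusted p = 0.00161) had 0.0753 as its adjusted p with an estimated correlation. Il1b was the only member of the latter to pass adjusted over the list alone. MHC class II genes had a median of -0.79 (adjusted p = 0.00067, and adjusted p = 0.322 with an estimated correlation), and H2-Aa had a log2 fold change of -1.49 (SE 0.44). The microglia, dissociation stress, mitochondrially encoded, cell cycle, monocyte and p53 lists were also called lower, with camera adjusted p from 5.91e-05 to 0.0376 and 0.322 to 0.541 as the range of the adjusted p with an estimated correlation. The iron and haem list and the erythroid list were called higher (adjusted p = 0.0401 and 0.0350, and adjusted p = 0.482 and 0.546 with an estimated correlation). The CNS-macrophage, microglia, MHC class II, inflammatory cytokine and dissociation stress lists were called with each library left out, and each of the other 6 lost its call without at least 1 library.

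Over the 500 most variable genes the 3 genotypes were weakly separated, with a pseudo-F of 1.16 and an exact permutation p of 0.04 over 4200 assignments of the 10 libraries. The p rose to 0.196 without homozygous replicate 2 and to 0.204 without wild-type replicate 2, and lay above 0.05 in 7 of the 10 cases with a library left out.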

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

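The tests of Mrc1, Esr1, MHC class II and Ccr2 below were chosen after the results were seen, and so were the splits counted with DESeq2 or without Mrc1. The other splits were set before they were counted. Among the 4 homozygous libraries, 10 of 141 named genes had a single library far from the others, where chance flags about 1 in 20, or 7.05. Homozygous replicate 4 stood apart for Esr1 (53.4 CPM, against 40.8 to 41.6 in the others), Il7r (1.60 against 0 to 0.205), Btg2 (228 against 134 to 148) and Ubr2 (52.0 against 71.8 to 75.6). Homozygous replicate 3 stood apart for Gja1 (3.78 against 12.1 to 13.5), Slc6a13 (5.68 against 0 to 0.954) and Enpp2 (102 against 0.436 to 13). Homozygous replicate 1 stood apart for Folr1 (0.436 against 0 to 0.0293), Ccl12 (730 against 321 to 389) and Irf1 (226 against 99.9 to 119). None of the list levels or library measures was flagged in this way.

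Chance assignment of the libraries was tested by counting calls over all splits into groups of the same sizes. For homozygous against wild type, 1 of 35 splits, the real one, gave as many as 9 genes by edgeR, and the highest of the others gave 0. The modified gene Mrc1 alone would set the real split apart, so the count was repeated without it. Then 1 of 35 splits, the real one, gave as many as 7 genes and the highest other gave 0. That is the smallest share that 35 splits allow, in a repeat chosen after the data had been seen. It argues against chance for the count as a whole, but not for each gene in it. For homozygous against heterozygous, 1 of 35 splits gave as many as 3 and the highest other gave 0. Without Mrc1 the real split gave 0, as did all 35 splits, so chance cannot be excluded for the calls other than Mrc1. With 3 against 3 there are 10 splits, too few for a share under 0.05, and the real value and the highest other were both 0. DESeq2 called 283 genes in the real split of homozygous and wild-type libraries, which 1 of 35 splits reached, but up to 179 in other splits. That highest other split put wild-type replicate 3 with homozygous replicates 1, 3 and 4.

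Mrc1 was lower with each copy of the knock-in allele. A smaller share of CNS-associated macrophages among the sorted homozygous cells would lower their other markers as well, but the median log2 fold change of the other 32 markers was 0.244 and none was as low as Mrc1. If each modified allele gave a fixed, smaller share of the counts of an unmodified one, the heterozygous level would lie at the midpoint of the others, and it was 1.08 times that midpoint (168 CPM above it, with an SE of 138). The values are therefore consistent with an additive loss per allele. Whether the cassette stops transcription, splits the transcript or only removes part of the counted exons stays open in a gene-level table.

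MHC class II genes and Ccr2 were lower in homozygous libraries. In wild-type libraries the other monocyte markers had a median of 2.42% of the Ccr2 level, with Ly6c2 at 2.58 CPM beside 129 CPM for Ccr2. This argues against classical monocytes as the main source of Ccr2 there, although Ms4a4c reached 75.9 CPM and Itgal 17.6 CPM. It does not address the change in homozygous libraries, where the monocyte list with Ccr2 was lower (8 of 10 fitted below 0, median -1.40, camera adjusted p = 0.0263, and adjusted p = 0.264 with an estimated correlation). That list contains Ccr2 itself, the only member lower when adjusted over the list alone. Its other 9 markers had a median of 3.13 CPM in wild-type libraries, so the list cannot decide the question. Fewer monocytes as a part of the pattern stay open. Fewer microglia cannot be told apart from a change within the macrophages. Within genotypes the MHC class II level and Tmem119 had a Pearson r of 0.132 (exact permutation p = 0.669, Spearman rho 0.152 with p = 0.675, and r = 0.110 without the 2 libraries farthest in Tmem119). The test assumes that microglia hold more of these transcripts than the macrophages do, which bulk libraries do not show, so it decides nothing here. A cohort difference cannot be excluded either, because 3 of the 4 homozygous mice have higher numbers in their titles than any other mouse; the remaining one, replicate 1, lay below every wild-type library for 13 of 15 of these genes, but it is a single library. A loss of an MHC class II-high, Ccr2-positive subset of macrophages, or a sort that depends on CD206, may also give this pattern, and neither was tested. Nor was a smaller share of B cells, whose markers are described above.

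Esr1 was higher in homozygous libraries. A candidate explanation is that reads from the oestrogen receptor part of CreERT2 were counted at Esr1, which would put heterozygous libraries between the others. Their mean was 7.04 CPM above wild type (SE 7.17; two-sided exact permutation p = 0.5, where 3 against 3 cannot go below 0.1) and differed from the midpoint of the other genotypes by -2.19 CPM (SE 7.05). It therefore cannot be told apart from either level, with replicates 1 and 2 at 23.8 and 28.5 CPM and replicate 4 at 46.1 CPM. A change of the mouse gene itself also stays open.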

How the results depend on the processing

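The fit without Mrc1 was added after the data had been seen. Mrc1 kept its direction and its side of the threshold under all 19 alternatives for homozygous against wild type (log2 fold change -2.91 to -2.77, adjusted p 3.81e-153 to 0.000243) and against heterozygous (-2.18 to -2.08, adjusted p 3.6e-85 to 0.00145). For heterozygous against wild type it ranged from -0.78 to -0.64 and passed only with DESeq2 (-0.71, adjusted p = 2.76e-07; 2.76e-07 to 1 over the alternatives). For homozygous against wild type, the log2 fold change of Ccr2 ran from -4.49 to -3.99, of Lyve1 from 0.80 to 0.89 and of Clec12a from -1.39 to -1.05. Ccr2 lost its call there with limma-voom and with the replicate block.

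The counts of called genes changed more, and the cause was not tested. With the title letter as a covariate, 17 genes were called for homozygous against wild type and 1 for homozygous against heterozygous. With only the 2 genotypes compared these were 2 and 1, and without robust estimation the latter was 1. With Mrc1 left out before the fit, 7 and 0 genes were called, the 7 all among edgeR's 9. DESeq2 called 283, 233 and 129 in the 3 comparisons, in the order homozygous against wild type, heterozygous against wild type and homozygous against heterozygous, and its calls included all 9 and all 3 of edgeR's. Leaving out each library in turn gave 2 to 12 genes for homozygous against wild type, 0 for heterozygous against wild type and 1 to 2 for homozygous against heterozygous. Slamf9 and Coro1a lost their call with any library left out, Gja1 and Clec12a with 9 of 10, Hgsnat and Cd52 with 8 and Lyve1 with 6, and none changed sign.

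The numbers of called lists, in the same order, were 2, 0 and 0 with an estimated correlation and 2, 0 and 3 with fry, and the last was 7 with the title letter. Leaving out a library gave 4 to 10, 0 to 6 and 8 to 13 lists. The T and NK cell list changed direction for heterozygous against wild type without wild-type replicate 2 (signed -log10 p of -2.29, adjusted p = 0.041, and -2.29 to 0.498 with each library left out). The pseudo-F ran from 1.07 to 1.33 with a library left out and stayed past its threshold under the other 5 alternatives.

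Whether the replicate numbers pair the mice was not settled. The deviations of same-numbered libraries correlated at -0.01 to 0.03 (median 0.0092), with 0 of 8 pairs above 0.1. The 25 other pairs had a median of -0.0041, and 5 of 10 libraries correlated best with their own number. Homozygous replicate 3 and heterozygous replicate 4, which share a title letter, reached only 0.048, so a limit of 0.1 can miss a shared factor. With the replicate block, 1 gene was called for homozygous against wild type and 1 for homozygous against heterozygous (Mrc1 in both), and 7 lists for the latter. On counts simulated from these libraries, edgeR called 2% of the genes changed 2-fold for homozygous against wild type, so changes of that size can be missed.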

Other observations

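The interaction of title letter and genotype below was tested only after the data had been seen. Haemoglobin transcripts varied between libraries of a genotype. Hbb-bs had 6504 and 13161 counts in homozygous replicates 2 and 3, or 177 CPM in the former, and was at 0.617 and 1.75 CPM in replicates 1 and 4, at 78.0 CPM in wild-type replicate 3 and at 37.7 CPM in heterozygous replicate 4. Its near-identical copies share reads. Il1b, an inflammatory cytokine, was at 1.09 to 5.70 CPM in homozygous, 26.7 to 61.4 CPM in heterozygous and 4.58 to 46.0 CPM in wild-type libraries, and did not pass over all genes between homozygous and wild type (log2 fold change -3.48, adjusted p = 0.321 by edgeR).

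Plxdc2, a transmembrane protein and the fourth tested gene after Mrc1 in the RefSeq order, was at 22.5 to 35.0 CPM in the 4 homozygous, 72.3 to 125 CPM in the 3 heterozygous and 48.0 to 246 CPM in the 3 wild-type libraries. Its log2 fold change of -2.23 (SE 0.47) between homozygous and wild type did not pass over all genes (adjusted p = 0.262 by edgeR), and it passed adjusted over the list alone among 12 neighbours of Mrc1. Among the 5 tested genes on either side of Mrc1, the others above 10 CPM in wild type were Stam (-0.07, SE 0.37), Nsun6 (-0.20, SE 0.57), Arl5b (0.03, SE 1.30) and St8sia6 (-4.97, SE 2.98, adjusted p = 0.819 by edgeR), and none passed. St8sia6 had 0 counts in wild-type replicate 1 and in 3 of the 4 homozygous libraries, and was at 10.9 and 30.6 CPM in wild-type replicates 2 and 3. Kptn had 0 counts in all 3 heterozygous libraries and 89 to 755 counts in every other library, and was at least 478-fold lower in heterozygous than in wild-type libraries against 3 counts over the group, without passing the test (adjusted p = 0.177 by edgeR).

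The interaction of title letter and genotype was fitted by edgeR with only 1 f library in the heterozygous and 1 in the wild-type group. With single libraries the fit cannot show that no gene differs by letter. For Mrc1 the log2 fold change of f libraries minus that of m libraries was 0.15 for homozygous against wild type. It was 0.04 for heterozygous against wild type and 0.11 for homozygous against heterozygous. No other tool was run on the interaction. Homozygous replicate 3, with the letter f, held 63 counts of Ddx3y and 0 of the other Y-linked genes, at 1.32% of the mean Y-linked CPM of the m libraries, and heterozygous replicate 2, with the letter m, held 80 counts of Xist, at 1.42% of the mean of the f libraries.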
